A study of Ovis aries with 14 samples.

How the data were processed

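Total RNA from the right lower lung lobe of 14 lambs was made into libraries with a stranded total RNA kit and sequenced, per the labels' protocols. The descriptions of the samples name 1 flow cell and lane for all libraries. The authors deposited 1 table of raw counts per gene, and all 14 of its sample columns hold whole-number counts with no normalization, as checked on the values. The submitters' processing notes name bcl2fastq, cutadapt 1.16, STAR 2.7.0f, Subread, featureCounts 1.6.3, DESeq2 1.22.2 and the genome build Oar_v3.1, with no role or order. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of overlapping, antisense and near-identical genes are therefore uncertain. Library totals ran from 23267448 to 31586235 counts.

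Groups and replicate numbers came from the sample titles, and the design was fixed before the data were examined. The table lists 27054 Ensembl gene identifiers, of which 4198 had no count in any library. The reference table used for names (assembly ARS-UI_Ramb_v3.0) carries Ensembl identifiers in 0 of its 35057 rows, so 0 identifiers matched a name. The 39 gene lists of cell types and pathways that had been fixed in advance are lists of symbols, 0 of their 697 symbols occur in the table, and none of the lists could be tested. The number of gene lists called, a planned result of each comparison, is therefore not reported. The planned rule for named genes required a symbol; it was applied without that requirement and limited to 2 identifiers per direction. It takes the largest changes among genes with an adjusted p under 0.05, a mean of at least 1 log2 CPM and no overlap between the groups, or the smallest p where fewer than 5 genes passed.

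Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr with its count minimum of 10) in R 4.3.3. All 14 libraries entered 1 fit with 5 group means, which leaves 9 residual degrees of freedom. The filter kept 17069 genes, which hold 99.97% of all counts, and left out 9985. Adjusted p-values are Benjamini-Hochberg values over these genes with a threshold of 0.05. The biological coefficient of variation was 26.0%. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. Ratios of a gene with 3 or fewer counts in a group are ratios of summed counts over summed effective library sizes with an exact conditional binomial interval of 95%. CPM values use the TMM-scaled library sizes, and log2 CPM for components and the index adds a prior count of 2. Genes that rose or fell at term against fetal end were tested as sets with camera (limma 3.58.1), two-sided, with a preset inter-gene correlation of 0.01 and again with an estimated one.

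Replicates of a group were compared before use. Chi-square per degree of freedom between 2 libraries of a group ran from 26.97 to 85.01, so no library repeated another, and Spearman correlations across genes ran from 0.976 to 0.987. On-off genes were those with a gap of over 3 between neighbouring sorted log2(CPM + 0.1) values and a highest CPM over 3, and the largest group of such genes with at least 4 libraries on each side was used as a covariate.

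The procedure was tested on simulated counts with 200 changed genes, 100 each at 2-fold and 4-fold. For IMV against NRS the test recovered 52% of the 2-fold and 70% of the 4-fold changes, with 8 false calls among 16793 genes tested. For IMV against fetal end it recovered 40% and 74% (16805 genes), for NRS against fetal end 43% and 77% (16789 genes), for fetal end against fetal start 46% and 75% (16763 genes) and for term against fetal end 50% and 75% (16797 genes). In a simulated set of 400 genes raised by 0.5 on the log2 scale in IMV, the median recovered against NRS was 0.506. The simulated genes varied independently of each other and had no on-off pattern, unlike the real ones. The shares recovered may therefore not hold for the real data.

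Alternatives were DESeq2 1.42.0, RLE scaling, no filter, a fit of only the 2 groups, the replicate number as a block, an animal identifier suffix as a covariate, fetal start as the reference, an estimated correlation and each library left out in turn. The on-off covariate, the term index, sets defined again without each term or fetal end library and the suffix covariate for these sets were added after the data had been seen.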

Results

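RNA was sequenced from the right lower lung lobe of lambs (Ovis aries), and the counts per gene of 14 libraries in 5 groups were compared. Preterm lambs received respiratory support for 3 days, either by invasive mechanical ventilation (IMV, n = 3), in which the lamb is intubated, or by noninvasive respiratory support through a mask (NRS, n = 3). Unsupported fetal lungs were taken at about the age at which support began (fetal start, n = 3, gestational ages labelled gd127, gd128 and gd131) and at about the age at which it ended (fetal end, n = 3, labelled gd135, gd134 and gd136). Lungs of the term group were labelled gd150 (n = 2), and both supported groups gd134. Each library came from an animal with its own identifier, so replicates were separate animals. The deposited counts summed to between 23267448 (NRS replicate 2) and 31586235 (IMV replicate 2) per library. The files give Ensembl gene identifiers and do not pair them with gene names, so genes are given here by identifier and described by how they changed across groups.

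The first principal component of log2 CPM held 25.6% of the variance and placed both supported groups between the fetal groups and term. Mean scores were 52.6 ± 9.65 in term lungs (SD, n = 2), 25.4 ± 2.94 with NRS (SD, n = 3) and 14.3 ± 11.3 with IMV (SD, n = 3). They were -29.6 ± 9.25 at fetal end (SD, n = 3) and -45.1 ± 23.2 at fetal start (SD, n = 3). The second component held 13.5% of the variance, and the IMV libraries scored 36.8 ± 14.2 (SD, n = 3) against -7.81 ± 21.9 with NRS (SD, n = 3). Fetal end replicate 2 scored 30.95 on this component, within the range of the IMV libraries.

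**Figure D1:**
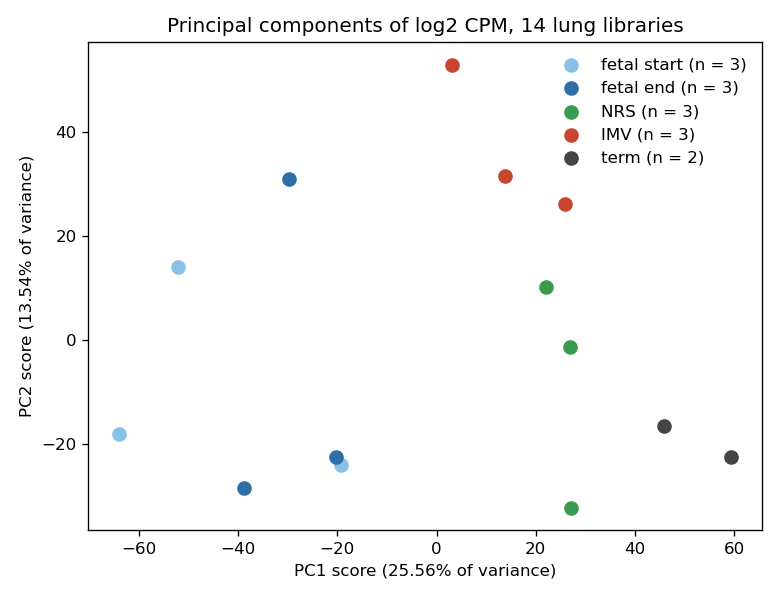
Scores of the 14 libraries on the first component (x axis, 25.56% of the variance) and the second component (y axis, 13.54%) of log2 CPM, 1 point per library, coloured by group. All 6 supported libraries have scores above 0 on the first component, all 6 fetal libraries have scores below 0, and the term libraries score 45.77 and 59.42.

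Genes that differ between fetal end and term were taken as a measure of how far other lungs had moved towards the term state. Term lambs were older than fetal end lambs, and the labels do not say whether they had been born or had breathed air, so the part of age in these changes was not separated here. In term lungs 648 genes were higher and 356 were lower than at fetal end (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 17069 genes tested), and these are called term-rising and term-falling genes below. The median log2 fold change was 0.83 for the genes that rose and -0.96 for those that fell, and 271 genes rose and 166 fell by 2-fold or more. ENSOARG00000003423 was nearly silent at fetal end, with 0 to 2 counts per library, and had 48.4 ± 20.9 CPM at term (SD, n = 2). The ratio of summed counts was 1899, with an exact 95% interval of 525 to 15690 that covers counting error only (edgeR adjusted p = 0.0121). Without fetal end replicate 3 this gene did not pass (edgeR adjusted p = 0.0501). ENSOARG00000004127 rose from 3.47 ± 1.42 CPM at fetal end (SD, n = 3) to 392 and 2640 CPM in the term libraries. Its log2 fold change was 8.77 ± 1.86 (SE, edgeR adjusted p = 0.024), and 6.82 without term replicate 2. The call of this gene was lost without any 1 of the fetal end libraries (edgeR adjusted p from 0.0555 to 0.0861). ENSOARG00000018650 was lower at term, 0.314 ± 0.150 CPM (SD, n = 2) against 6.41 ± 2.97 CPM (SD, n = 3), a log2 fold change of -4.33 ± 0.88 (SE, edgeR adjusted p = 0.0209). It did not pass without fetal end replicate 3 (edgeR adjusted p = 0.0566). With 1 term library left its log2 fold change was -3.91 (without term replicate 2) and -4.92 (without term replicate 3). ENSOARG00000008077 had 1 and 2 counts in the term libraries against 549 to 904 at fetal end, a ratio of 0.00199 with an exact 95% counting interval of 0.000411 to 0.00583 (edgeR adjusted p = 0.0406). This call was lost without any 1 of the fetal end libraries (edgeR adjusted p from 0.0575 to 0.0858). With 1 term library left the log2 fold change was -8.45 (without term replicate 2) and -9.38 (without term replicate 3). Counts of this gene also ranged from 1 to 503 among the IMV libraries, so its presence varied within a group. The group of 2 term libraries limits this comparison, and both term lambs have animal identifiers ending in 18 where all 3 fetal end lambs have 19. The number of changed genes was 44 without term replicate 2 (34 higher, 10 lower), 521 without term replicate 3 (445 and 76), 265 without fetal end replicate 1 (172 and 93), 844 without fetal end replicate 2 (410 and 434, so that more genes fell than rose) and 114 without fetal end replicate 3 (70 and 44). It was 141 in a fit of only these 2 groups.

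Fetal end against fetal start covers development in utero over about the support period. A single gene, ENSOARG00000006431, was higher at fetal end than at fetal start, at 4.21 ± 0.84 CPM against 0.457 ± 0.191 CPM (SD, n = 3 each), a log2 fold change of 3.19 ± 0.39 (SE, edgeR adjusted p = 0.0422), and 0 genes were lower. It stood at 3.65 ± 0.36 CPM at term (SD, n = 2), 2.84 ± 1.23 with NRS and 2.09 ± 0.43 with IMV (SD, n = 3 each), all above fetal start. The lower gene with the smallest p, ENSOARG00000001680, did not pass in edgeR, at 0.959 ± 0.474 CPM against 7.68 ± 4.16 CPM (SD, n = 3 each, edgeR adjusted p = 0.244). DESeq2 called it (DESeq2 adjusted p = 1.2e-05). At an unadjusted p under 0.05 the edgeR test counted 1321 genes, where chance gives 853 on average, and DESeq2 called 122 at its adjusted threshold. Genes vary together, so the count of an arbitrary grouping can lie far from that average. The call was lost without any 1 of the fetal end libraries or without fetal start replicate 2 (0 genes each). It was also lost without fetal start replicate 1, where 3 other genes passed, and 5 genes passed without fetal start replicate 3. Fetal start replicate 3 was the oldest of its group (labelled gd131) and scored -19.3 on the first component, where the other libraries of the group scored -52.1 and -64.0.

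IMV against fetal lungs of about the same age asks how lungs after 3 days of invasive ventilation differed from unsupported ones. The groups also differ in birth and in animal identifiers, which end in 17 or 18 for IMV and in 19 for fetal end. Ventilation itself was therefore not separated, and neither was NRS below, whose identifiers end in 18. After IMV 71 genes were higher and 46 were lower than at fetal end, with median log2 fold changes of 1.30 and -0.94, and 22 genes were higher by 4-fold or more. ENSOARG00000003423, the gene that was nearly silent at fetal end, had 16.7 ± 4.27 CPM after IMV (SD, n = 3), and the ratio of summed counts was 654 with an exact 95% counting interval of 181 to 5403 (edgeR adjusted p = 0.0427). This call was lost without any 1 of the IMV libraries, and without fetal end replicate 1 or 3. ENSOARG00000004367 rose from 2 to 5 counts per library at fetal end to between 38 and 510, a log2 fold change of 5.63 ± 1.11 (SE, edgeR adjusted p = 0.046) that was 3.31 without IMV replicate 1 (edgeR adjusted p = 0.102). Its call was also lost without IMV replicate 2, without fetal end replicate 1 or 3, and in a fit of only these 2 groups. ENSOARG00000000021 fell to 1.31 ± 0.71 CPM from 37.7 ± 5.22 CPM (SD, n = 3 each), a log2 fold change of -4.83 ± 0.95 (SE, edgeR adjusted p = 0.046), although it stood at 59.5 ± 4.30 CPM at term (SD, n = 2) and varied from 1.38 to 25.5 CPM at fetal start. ENSOARG00000010688 fell to 48.3 ± 20.7 CPM from 515 ± 184 CPM (SD, n = 3 each), a log2 fold change of -3.41 ± 0.56 (SE, edgeR adjusted p = 0.0367). The calls of ENSOARG00000000021 and ENSOARG00000010688 were both lost without IMV replicate 1 or 2, or without fetal end replicate 1 or 3. That of ENSOARG00000000021 was also lost without IMV replicate 3. All 117 changed genes had the same sign against fetal start, with the same IMV libraries, and 83 of them also passed the test there. The count depended on single libraries: it was 0, 6 and 52 without IMV replicate 1, 2 and 3, and 0, 644 and 1 without fetal end replicate 1, 2 and 3. Most of the 644 genes were lower after IMV (419, with 225 higher), the opposite balance to that with all libraries. DESeq2 called 1527 genes, which included all 117, and with a covariate for the on-off genes described with the comparison of IMV and NRS the count was 6.

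After NRS 52 genes were higher and 21 were lower than at fetal end, with median log2 fold changes of 2.48 and -0.84. Of the genes that rose, 33 did so by 4-fold or more, and 0 genes fell by that much. ENSOARG00000003423 again had the largest rise, to between 7.90 and 202 CPM, with a ratio of summed counts of 3173 and an exact 95% counting interval of 878 to 26210 (edgeR adjusted p = 0.0167). NRS replicate 3 carries most of this ratio: the log2 fold change was 11.40 with all libraries and 9.45 without it (edgeR adjusted p = 0.00773), and the call was lost without any 1 of the fetal end libraries. ENSOARG00000014101 rose from 0 to 3 counts per library at fetal end to between 108 and 303 counts, or 7.23 ± 4.11 CPM (SD, n = 3, edgeR adjusted p = 0.0245), where IMV libraries had 1.98 ± 1.34 CPM (SD, n = 3). ENSOARG00000025904 fell to 17.2 ± 2.36 CPM from 48.3 ± 6.72 CPM (SD, n = 3 each), a log2 fold change of -1.49 ± 0.24 (SE, edgeR adjusted p = 0.0297), and IMV libraries stood at 17.3 ± 3.50 CPM (SD, n = 3). ENSOARG00000013219 fell to 1.19 ± 0.42 CPM from 4.37 ± 0.41 CPM (SD, n = 3 each), a log2 fold change of -1.88 ± 0.31 (SE, edgeR adjusted p = 0.0301). The call of ENSOARG00000025904 was lost without any 1 of the NRS or fetal end libraries. That of ENSOARG00000013219 was lost without any of these except NRS replicate 3. ENSOARG00000014101 lost its call without NRS replicate 3 and without any 1 of the fetal end libraries. All 73 changed genes had the same sign against fetal start, with the same NRS libraries, and 58 also passed there. The count was 16, 44 and 19 without NRS replicate 1, 2 and 3, and 3, 13 and 2 without fetal end replicate 1, 2 and 3. It was 648 with DESeq2, 114 in a fit of only these 2 groups and 249 with the on-off covariate.

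The changes after the 2 kinds of support were compared with each other. Against fetal end 18 genes were higher and 9 were lower after both IMV and NRS, and 0 went in opposite directions. Independent lists of these sizes would share 0.216 higher and 0.0566 lower genes. Because both comparisons use the same fetal end libraries, unchanged groups were simulated against those controls. The covariance of the log2 fold changes across genes was 0.336, against a simulated mean of 0.097 and a highest value of 0.107 in 20 simulations (correlation 0.640 against a simulated mean of 0.498, across genes, which are not independent replicates). The simulated genes varied independently of each other, unlike real genes. The simulated range may therefore be too narrow, and it cannot exclude the shared controls as a source of this covariance. With no library in common, IMV against fetal end and NRS against fetal start shared 30 higher and 8 lower genes, and IMV against fetal start and NRS against fetal end shared 33 higher and 8 lower genes. Of the 18 genes higher after both kinds of support, 13 were term-rising, and all 9 lower genes were term-falling, with fetal end also in the comparison that defined those classes. The overlap of 27 genes fell to 0 without IMV replicate 1, fetal end replicate 1 or fetal end replicate 3, to 1 without IMV replicate 2, to 4 without NRS replicate 1, to 11 without NRS replicate 3 and to 12 without fetal end replicate 2. With the on-off covariate it was 3.

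**Figure D2:**
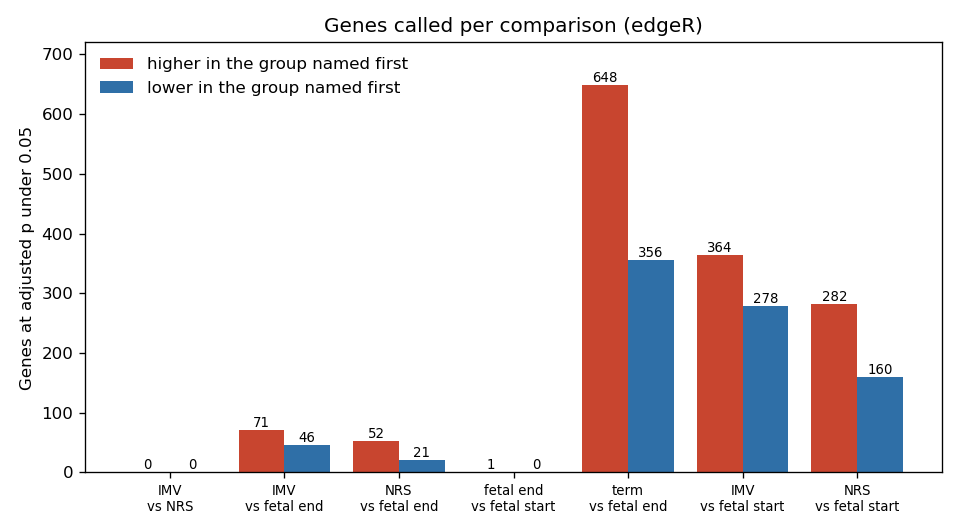
Number of genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test (y axis) in 7 comparisons (x axis), with bars for genes higher and lower in the group named first. Term against fetal end gave 648 higher and 356 lower genes, and IMV against NRS gave 0 of either.

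Term-rising and term-falling genes were followed in the supported lambs against fetal start, a comparison that shares no library with the one that defined them. Term-rising genes were higher after IMV, with a median log2 fold change of 0.40 (quartiles 0.21 to 1.06), and 602 of the 648 genes (92.9%) had a positive fold change. Term-falling genes were lower after IMV, with a median of -0.34 (quartiles -0.60 to -0.09), and 289 of 356 (81.2%) had a negative one. After NRS the medians were 0.40 (quartiles 0.20 to 1.35) and -0.40 (quartiles -0.64 to -0.22), with 615 of 648 genes (94.9%) positive and 317 of 356 (89.0%) negative. The other genes had medians between -0.015 and 0.013. All 4 sets stood apart in camera's two-sided test with a preset correlation of 0.01 (adjusted p from 5.47e-55 to 3.92e-20, over 6 set tests), and all 4 passed with an estimated correlation (adjusted p from 0.0044 to 0.00681). All 4 medians kept their sign, and passed with the preset correlation, when the sets were defined again without each term or fetal end library. The estimated correlation was not used for those sets. Both kinds of support were set against the same fetal start libraries here, so these results are not independent of each other. The supported lambs (labelled gd134) were also older than the fetal start lambs (labelled gd127, gd128 and gd131). Age and support were therefore not separated in these medians. Fetal end lungs are of about the supported age but helped to define the sets, so they cannot separate them here. For the single genes below, fetal end against fetal start covers about the same step in age and called 1 gene. With all libraries IMV and NRS against fetal start called 642 and 442. This argues against age as the whole source of those counts, and a part of age stays open.

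Single genes showed the same pattern. Against fetal start 364 genes were higher and 278 lower after IMV, and 282 were higher and 160 lower after NRS. Of the 364 genes higher after IMV, 37.4% were term-rising, where 3.8% of all tested genes were, and 1 gene was term-falling. Of the 282 genes higher after NRS, 49.6% were term-rising and 0 genes were term-falling. Of the genes that were lower, 49 of 278 after IMV (5.8 by chance) and 57 of 160 after NRS (3.3 by chance) were term-falling, and 0 were term-rising after either. These counts rest on single libraries. Leaving out 1 library of the groups compared left 4 to 169 term-rising genes called higher after IMV (4 without fetal start replicate 2, 9 without IMV replicate 1 and 20 without IMV replicate 2). After NRS it left 6 to 236, against 140 with all libraries (6 without fetal start replicate 2). Term-falling genes called lower ranged from 1 (without IMV replicate 1 or fetal start replicate 2) to 56 after IMV, and from 4 (without fetal start replicate 2) to 94 after NRS.

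A term index was computed per library after the data had been seen, as the mean log2 CPM of the term-rising genes minus that of the term-falling genes, scaled so that fetal end has a mean of 0 and term a mean of 100. The index was 56.7 ± 2.77 after NRS, 48.1 ± 5.69 after IMV and 4.03 ± 13.9 at fetal start (SD, n = 3 each). Each of the 6 supported libraries lay above all 6 fetal libraries, the highest of which was fetal start replicate 3 at 20.03. The difference from fetal start was 44.0 for IMV and 52.7 for NRS, each with p = 0.1 in an exact two-sided permutation test, the smallest p that 3 against 3 animals allow. IMV libraries were lower than NRS libraries by a mean of -8.65, from 41.7 to 52.6 against 54.1 to 59.6, with the same exact two-sided permutation p = 0.1. With the genes and the scale defined again without each of the 14 libraries, every supported library stayed above every fetal one. The order of IMV and NRS did not hold: the difference of means ran from -13.31 (without term replicate 2) to 6.74 (without fetal end replicate 2), where IMV was higher, and it was -3.74 without IMV replicate 2. The ends of the scale were set on the libraries that chose the genes, so the distance between fetal end and term is stretched by that choice. The low place of the fetal end libraries follows from that choice too. Only the fetal start libraries, from younger lambs than the supported ones, therefore test whether supported libraries lie above fetal ones.

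**Figure D3:**
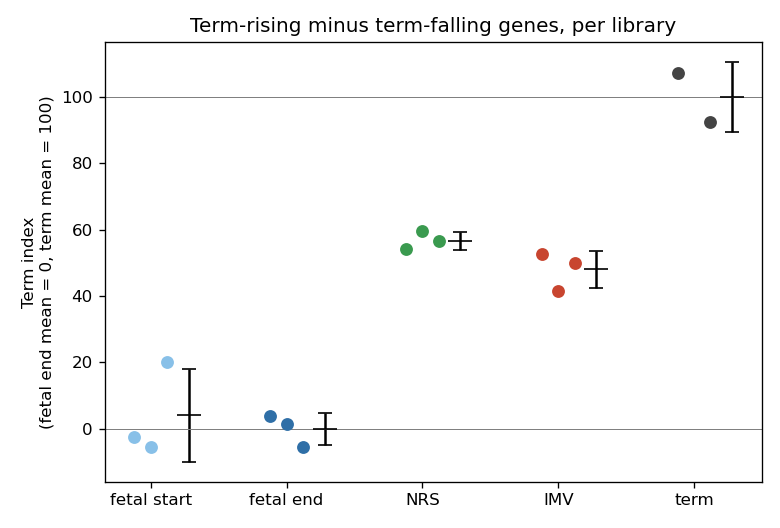
Term index of each library (y axis, no unit, fetal end mean 0 and term mean 100) by group (x axis), with the mean and SD beside the points. NRS libraries lie between 54.06 and 59.59 and IMV libraries between 41.66 and 52.56, while the 6 fetal libraries lie between -5.39 and 20.03.

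The series sets invasive ventilation against noninvasive support, and in this direct comparison 0 genes passed in edgeR's quasi-likelihood test (smallest adjusted p = 0.360). At an unadjusted p under 0.05 there were 1854 genes, 1024 higher and 830 lower with IMV, where chance gives 853 on average. DESeq2 called 81 genes higher and 50 lower with IMV. The values of 19.1% of genes did not overlap between the groups, where chance gives 10% on average for 3 against 3. Genes vary together, so an arbitrary grouping can lie far from such averages. Other assignments of the on-off state described below, within the fetal start, fetal end and term groups, gave 419 to 1703 genes under 0.05. Those counts are for a covariate over these groups and not for 3 lambs against 3. They show only how widely such counts vary, and other splits of the IMV and NRS libraries were not counted in this way. The genes with the smallest p did not pass. ENSOARG00000008321 had 41.4 ± 4.64 CPM with IMV and 25.8 ± 0.43 CPM with NRS (SD, n = 3 each), and its log2 fold change was 0.68 ± 0.10 (SE). ENSOARG00000017587 had 3.67 ± 0.35 CPM with IMV and 1.18 ± 0.28 CPM with NRS (SD, n = 3 each). In the opposite direction ENSOARG00000012938 had 78.1 ± 5.33 CPM with IMV and 111 ± 15.1 CPM with NRS, and ENSOARG00000013455 had 1.01 ± 0.40 CPM with IMV and 4.08 ± 1.38 CPM with NRS (SD, n = 3 each). Each of these 4 genes had an edgeR adjusted p of 0.36. DESeq2 called all 4 (DESeq2 adjusted p from 5.6e-05 to 0.00455), so their verdict turns on the method. The animal identifiers of IMV replicates 1 and 2 end in 17, and those of IMV replicate 3 and all 3 NRS lambs in 18, so the groups also differ in this suffix.

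Term-rising and term-falling genes were also compared between IMV and NRS. The median log2 fold change of IMV over NRS was -0.03 for the term-rising genes (quartiles -0.29 to 0.11, 358 of 648 negative) and 0.10 for the term-falling genes (quartiles -0.13 to 0.31, 214 of 356 positive). With the preset correlation both passed in camera's two-sided test (adjusted p = 0.0408 and 0.00844). With an estimated correlation neither passed (adjusted p = 0.594 and 0.32), and with the identifier suffix as a covariate the medians were -0.014 and 0.052 and neither passed (adjusted p = 0.246 each). With the on-off covariate they were -0.175 and 0.137 (adjusted p = 8.22e-12 and 1.28e-05 with the preset correlation). Other assignments of the on-off state gave medians from -0.143 to 0.14 for the term-rising genes. The medians were -0.003 and 0.054 without IMV replicate 2 (adjusted p = 0.431 and 0.194), and the term-rising genes also did not pass without NRS replicate 2 (adjusted p = 0.198). With sets defined again without fetal end replicate 2 the term-falling genes were lower with IMV (median -0.347, adjusted p = 3.47e-15), the reverse of the direction with all libraries, and the term-rising genes did not pass (adjusted p = 0.152). The tests with a covariate, with a library left out or with sets defined again used the preset correlation only. Their small p-values may not hold with an estimated one, which was not used there.

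The IMV and NRS lambs also differed completely in 3 genes that were either on or off in each library of the series, a pattern looked for after the data had been seen. ENSOARG00000025367 had 1729 to 3291 counts in 8 libraries and 0 to 5 in the other 6. ENSOARG00000024320 had 301 to 618 counts in the same 8 libraries and 0 to 2 in the others, and ENSOARG00000023683 had 137 to 329 counts and 0 counts. These genes were on in all 3 IMV libraries, in 0 of 3 NRS libraries, in 2 of 3 fetal start libraries, in 2 of 3 fetal end libraries and in 1 of 2 term libraries. In the fit of all groups they did not pass for IMV against NRS, at log2 fold changes of 9.73 to 11.62 (edgeR adjusted p = 0.36 each). That test can therefore miss even a complete difference. In a fit of only the IMV and NRS libraries 2 genes passed, and both were among these 3 (ENSOARG00000025367, edgeR adjusted p = 0.000574, and ENSOARG00000024320, edgeR adjusted p = 0.0255). In fits of all groups with 1 library left out, 1 gene passed without IMV replicate 2. It was lower with IMV and so was not among these 3. Without NRS replicate 1, 2 genes passed, both higher with IMV and not identified here. Every difference between the IMV and NRS groups given here coincides with the state of these 3 genes.

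**Figure D4:**
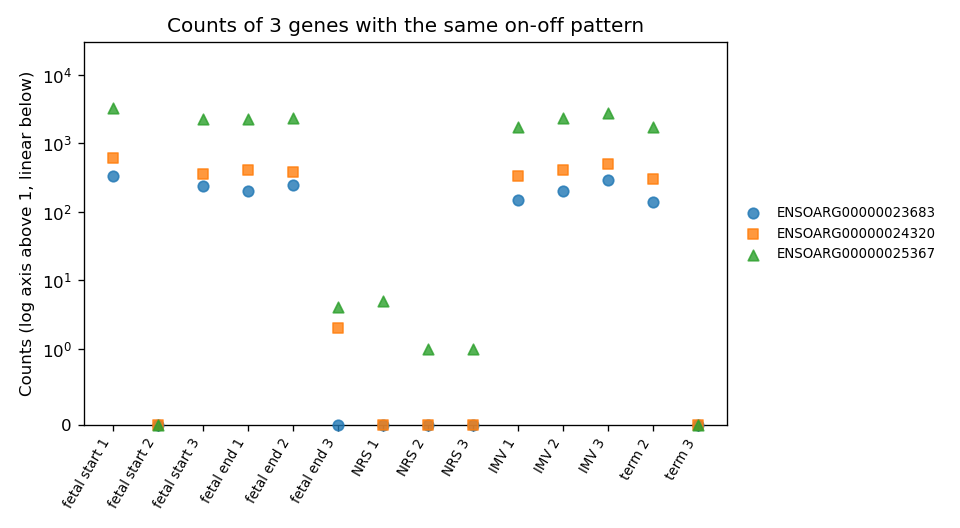
Counts of the 3 on-off genes (y axis, log axis above 1 count and linear below) in each of the 14 libraries (x axis, group and replicate number), 1 marker shape per gene. The 3 IMV libraries have 151 to 2796 counts of each gene, and the 3 NRS libraries have 0 to 5.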

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

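The on-off covariate, the term index, the sets defined again and the identifier suffix as a covariate for the sets were chosen only after the data had been seen. With RLE scaling and with no filter, all 12 planned results stayed within 1.5 times of their count or on the same side of the threshold, with the same sign. The suffix of the animal identifiers as a covariate left 0 genes for IMV against NRS, as without it, and medians of -0.014 and 0.052 for term-rising and term-falling genes, which did not pass. DESeq2 called 81 genes higher and 50 lower for IMV against NRS (1.3e+02 in all), 1527 for IMV against fetal end, 648 for NRS against fetal end, 122 for fetal end against fetal start and 2427 for term against fetal end. A fit of only the 2 groups gave 2, 146, 114, 0 and 141 genes in that order, and the on-off covariate gave 0, 6, 249, 0 and 1501. The overlap of 27 genes was 3 with the on-off covariate and 41 between IMV against fetal start and NRS against fetal end. Fetal start as the reference gave 642 genes for IMV and 442 for NRS. With an estimated correlation the medians of -0.029 and 0.096 for term-rising and term-falling genes in IMV against NRS did not pass. Leaving out 1 library at a time, which also leaves fewer samples, gave 0 to 2 genes for IMV against NRS, 0 to 644 for IMV against fetal end, 2 to 44 for NRS against fetal end, 0 to 5 for fetal end against fetal start, 44 to 844 for term against fetal end and 0 to 27 for the overlap. With 1 term library left, that library was assumed to vary like the other groups. Sets were kept when an IMV, NRS or fetal start library was left out, and defined again without a term or fetal end library. The medians in IMV against NRS ran from -0.18 to -0.003 for term-rising genes and from -0.347 to 0.152 for term-falling genes, whose sign reversed without fetal end replicate 2, and those against fetal start kept their sign and passed with the preset correlation, the only one used there. With its genes and scale defined again without each of the 14 libraries, the term index of IMV ran from 36.59 to 64.35, that of NRS from 45.98 to 63.68 and IMV minus NRS from -13.31 to 6.74, with the sign reversed without fetal end replicate 2. Named genes kept their sign in all 216 values under the alternatives fixed in advance, with 68 no longer past the threshold and 8 newly past it. Some of the 216 values belong to genes that did not pass with all libraries and so could not lose a call. Genes named for the largest change had been chosen for no overlap between groups, so leaving out 1 library could hardly reverse their sign. The cause of these shifts was not tested, apart from the fewer samples named. The gene lists gave no value, since none could be tested. Depth limits genes with few counts, such as those with 0 to 5 counts per library in 1 group.

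Replicate numbers did not pair the libraries: 3 of 18 same-numbered pairs of different groups had a correlation of deviations over 0.1, and the median was -0.022. With the replicate number as a block the counts were 0 for IMV against NRS, 4 for IMV against fetal end, 15 for NRS against fetal end, 0 for fetal end against fetal start, 450 for term against fetal end and 1 for the overlap, and all set medians kept their sign and side of the threshold.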

Other observations

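Besides the 3 genes that split the IMV and NRS lambs, other genes were on in some animals and off in others. In all, 52 genes had such a gap, and 17 of them were on in 1 library only, 10 in fetal end replicate 1, 5 in IMV replicate 1, and 1 each in term replicate 3 and fetal start replicate 3. A group of 5 genes was on in IMV replicate 2 and fetal end replicate 2 and off in the other libraries. Of all pairs of libraries from different groups with 3 replicates, the same pair had the highest correlation of deviations from the group means across genes (0.288), and both had high scores on the second component (52.9 and 30.95). ENSOARG00000000016, chosen after its values were seen, had 14 counts in IMV replicate 3 and 12572 to 24997 in each of the other libraries.

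The tests of the fetal end lambs below, and the splits of gene counts, were chosen only after the results were seen. The supported groups differed from fetal end in 117 (IMV) and 73 (NRS) genes, and all 3 fetal end lambs have animal identifiers that end in 19, a suffix no other lamb has. The term lambs, which differed from fetal end in 1004 genes, all have the suffix 18. A difference that goes with the suffix of the fetal end lambs could produce such changes, and the called genes should then not move between groups without that suffix. Such a difference should also show between fetal end and fetal start, whose lambs have the suffixes 17 and 18. That comparison called 1 gene, and 0 to 5 with 1 library left out. The genes called for IMV, NRS and term were followed in comparisons that share no library with the one that called them. The genes called for IMV had a median log2 fold change, in the direction called, of 0.539 in NRS against fetal start (0.467 to 0.547 leaving out 1 library), and the highest other of 10 splits gave 0.327. Those called for NRS had 1.324 in IMV against fetal start (1.24 to 1.38, highest other 0.477). Those called at term had 0.389 in IMV and NRS together against fetal start (0.335 to 0.455, highest other of 84 splits 0.283). Where they were called, the median sizes were 1.184 for IMV, 1.713 for NRS and 0.897 for term. In the test of the term genes 1 of the 84 splits, the real one, gave a value as large. The tests for IMV and NRS have 10 splits each, too few for a share under 0.05. These values argue against the suffix as the whole source of the term changes, and with less weight for IMV and NRS. A part in the size of the changes or in single genes stays open. The supported lambs were also older than the fetal start lambs. In these medians an effect of support, of birth itself or of this age difference stays open and was not separated here.

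The median log2 fold change of the term-rising genes between IMV and NRS was -0.029, with 358 of 648 genes negative and 0 called, and it did not pass with an estimated correlation (camera adjusted p = 0.594). If this is a difference at all, an animal trait marked by the 3 on-off genes, for which sex is a candidate explanation that the labels do not give, might account for it. With the on-off state as a covariate, estimated from the fetal and term libraries, the median was -0.175, and it ran from -0.202 to -0.124 without each of the 14 libraries. The bound set before this test, a median that keeps its sign and at least 50% of its size, was met. It was too weak, since the effect of the trait is estimated from 1 library with the genes off in each of the fetal start, fetal end and term groups, and 17 other assignments of the state within these groups gave -0.143 to 0.14, a shift of up to 0.168 against 0.147 for the real one. The trait therefore cannot be told apart as a source of this median. The other assignments were brought in, and the bound set aside, only after the result was seen. Library depth was tested by thinning every library to the smallest total, which gave -0.035, but without single libraries the value ranged from -0.055 to -0.014, so depth cannot be told apart at this size. Of 10 splits of the 6 libraries, 6 gave a median as large as the real one, the highest other being 0.064, so the pattern itself may be no more than variation between animals. The suffix of the animal identifiers, 17 in 2 of the 3 IMV lambs and in 0 NRS lambs, is not excluded either, since the median was -0.014 with it as a covariate.

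Whether the trait behind the 3 on-off genes also changes many other genes was tested over the 18 ways to assign on and off within the fetal start, fetal end and term groups. The real assignment called 1 other gene, ENSOARG00000010016 (named after its values were seen), which was lower in the libraries with the 3 genes on (log2 difference -2.27, edgeR adjusted p = 0.0131). The highest of the other assignments called 4 genes, and 2 of them called at least as many as the real one. At an unadjusted p under 0.05 the real assignment had the most genes, 2123 against at most 1703. The bound set before this test, at least 1 other assignment with as many called genes, was met, which counts against a wider effect. That bound was too weak, since it rests on at most 4 called genes while the unadjusted count points the other way and 18 assignments are too few for a share under 0.05. A wider effect of the trait therefore cannot be told apart from chance. The unadjusted count was brought in, and the bound set aside, only after the result was seen.

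With 3 animals against 3 there are 10 splits, too few for a share under 0.05, so only the real value and the highest other are given. IMV against NRS gave 0 genes and the highest other split 0, with all 10 splits alike. IMV against fetal end gave 117 genes and at most 0 in the others, NRS against fetal end 73 and at most 3, and fetal end against fetal start 1 and at most 0, each reached by 1 split, the real one. The term-falling genes in IMV against NRS had a median of 0.096, and the highest other was 0.055. Against fetal start the medians of term-rising genes were 0.401 for IMV (highest other 0.254) and 0.397 for NRS (0.217), and those of term-falling genes -0.344 for IMV (largest other -0.220) and -0.396 for NRS (-0.243). For the 27 genes shared by IMV and NRS against fetal end, 100 splits of the 9 libraries were drawn, and 1, the real one, gave as many, with 6 in the highest other. Chance assignment of these libraries can be excluded for an overlap of this size. Since the other splits called few genes to share, this shows only that the supported groups differ from fetal end, and not that they share more genes than 2 such lists with common controls would.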
